A study of Rattus norvegicus with 4 samples.

How the data were processed

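RNA was measured in single nuclei of frozen brain from 4 adult male Sprague Dawley rats of about 400 g, each killed 6 h after an intraperitoneal injection of cisplatin at 6 mg/kg. From each brain, 3 punches of about 1 mm3 that covered the area postrema and the left and right nucleus tractus solitarius were pooled into 1 library, made with the 10x 3' chemistry, version 3.1. The 4 libraries form 1 group, so each rat is 1 replicate and n = 4, except in the neuron clusters N13, N18, N19 and N25, which were tested in 3 animals. No vehicle-treated group was analysed here, and no effect of cisplatin can be tested from these 4 libraries. All tests compare classes of nuclei, or clusters of neurons, within the same animals.

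The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 3.1 on the Rnor_6.0 genome. They are not filtered to nuclei, so that empty droplets are included. Whether intronic reads were counted is not stated. The features comprise 32883 genes, of which 37 are mitochondrial, and every matrix column was used. Genes are named as the features give them. The libraries held 98867283, 106417740, 105684534 and 77620846 UMIs in replicates 1 to 4. Counts of genes differed between each pair of libraries far beyond counting error (chi-square per degree of freedom 104.11 to 283.84), so no library is a copy of another.

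Droplets were called as nuclei at a UMI limit set per library, the 99th percentile of the top 5000 barcodes divided by 10 and at least 500, and with at least 300 genes. The limits were 1770.5, 1715.1, 2091.3 and 1500.2 UMIs, and 52668 droplets passed them. Droplets whose mitochondrial share exceeded that of their library's own empty droplets (500 to 800 UMIs) were left out, at limits of 10.7%, 14.8%, 13.8% and 11.3%, which left 36406. Scrublet scores (scikit-image 0.26.0 and scanpy 1.11.5) ranked doublets within each library. The automatic threshold marked 0.033%, 7.40%, 0.013% and 0.012% of nuclei, so the 8% with the highest scores were removed in every library instead, leaving 33492 nuclei. The median nucleus held 3077, 2763, 3332 and 2697 UMIs, and 1886, 1620, 1892 and 1725 genes. The most common size of an empty droplet was 739.6, 849.1, 889.1 and 587.4 UMIs, or 24.0%, 30.7%, 26.7% and 21.8% of the median nucleus. Free RNA was therefore a sizeable part of each nucleus's counts.

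All nuclei were clustered together, without batch correction, on counts scaled to 10000.0 per nucleus and log-transformed, with 2500 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9). Genes of the lists described next were left out of these features. Clusters were named from marker lists fixed beforehand, and the names stand for expression like that of a class, since no tissue section or sort was available. Clusters that correlated with empty droplets at 0.93 or more (1112 nuclei) and clusters with high doublet scores or markers of a second class (967 nuclei) were left out. Among the latter, a cluster led by Arhgef33, Itpr1, Dgkh, Fam107b, Trabd2b and Slc1a6 matched none of the classes other than neurons. It was left out for its doublet scores and was not scored for neuron markers, so whether its nuclei are doublets is not known. It held 0, 22, 21 and 16 nuclei in replicates 1 to 4, and so was missing from replicate 1. Neuron clusters whose lowest share in an animal was under 5% of the highest (1583 nuclei) were set apart as patchy neurons and not tested. This left 31413 named nuclei in the shares. Neurons were clustered again into 28 clusters, N0 to N27, and called inhibitory, glutamatergic, cholinergic motor or unassigned. Catecholaminergic markers were counted but gave no class of their own. The thresholds for naming clusters, the mitochondrial limits, the doublet share and the rule on patchy neurons were set after the clusters had been seen, and before any list gene was tested.

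The design, the alternatives and 9 gene lists were fixed before the data were examined. The lists comprised p53 target genes (28 of 30 members matched a feature), immediate early genes (21 of 21), receptors for emetic, appetite and gut signals (35 of 35), neuropeptide genes (21 of 21) and cytokine and NF-kB response genes (22 of 23). The others were glucocorticoid-responsive genes (17 of 18), platinum transport, metallothionein and NRF2 genes (20 of 24), crosslink and nucleotide excision repair genes (25 of 27) and barrier and fenestration genes (11 of 12). Together they named 201 genes, of which 192 matched by symbol, and 10 genes stood in more than 1 list. The glucocorticoid list shared Nfkbia with the cytokine list, Mt1 and Mt2A with the platinum list, and Cdkn1a and Ddit4 with the p53 list. Calls of these lists in the same class are therefore not independent.

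Raw counts were summed per animal and class, or per animal and neuron cluster, with at least 20 nuclei per sum, for classes and clusters with such sums in at least 3 animals. Genes were filtered with filterByExpr, libraries normalized by TMM, and sums tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) with the animal as a block. Each class was compared with the mean of the other classes, each neuron cluster with the mean of the other clusters, and inhibitory with glutamatergic neurons. These means were taken over fitted log levels, with each class or cluster counting equally. Benjamini-Hochberg adjustment ran over all genes tested in a contrast, and counts are also given adjusted over the list alone. Lists were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, adjusted over all 99 pairs of list and class, and repeated with an estimated correlation. Calls are at an adjusted p under 0.05, all tests are two-sided, and levels are CPM (counts scaled to a common total per sum) as mean ± SD over the animals. Fold changes are on the log2 scale, ± SE. Shares of nuclei with a UMI were taken after each nucleus had been thinned to 1500 UMIs. Confidence intervals of single shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

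Co-detection of receptor genes in neurons was compared with the number expected within deciles of UMIs of each animal, with a pseudocount of 0.5, for 15 pairs of genes. It was tested by an exact sign-flip test over 4 animals, which cannot go below p = 0.125. Tested on simulated data, the class model recovered 87.0% of genes changed by a log2 value of 1 and 100.0% of those changed by 2, with 4.6% of its calls false. The inhibitory against glutamatergic model recovered 100.0% of both, with 8.7% of calls false, and the cluster model 93.0% and 100.0%, with 4.0% false. The simulation gave every class and animal the same mean profile and changed 100 genes by each value in a single class. In the data far more genes differed, as in neurons with 4432 higher and 4678 lower of 12268. These rates therefore do not measure the accuracy of the models on these data.

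The genes named were fixed by rule. In each contrast and list the rule takes up to 3 genes in each direction with the largest fold change among those with an adjusted p under 0.05 that lay on the same side in every animal. It adds, whatever their result, Cdkn1a, Mdm2, Gdf15, Fos, Gfral, Glp1r, Calcr, Casr, Htr3a, Fkbp5 and Plvap. Other genes were named after their values were seen, mainly where they made up a small count. The alternatives fixed beforehand were leaving out each replicate in turn, a fixed limit of 1000 UMIs, keeping doublets, centring the features within each animal, a Leiden resolution of 2.0, DESeq2 size factors (DESeq2 1.42.0), no filter on low counts, the DESeq2 Wald test, no replicate block and the estimated correlation. For co-detection they were no depth strata and doublets kept. Subtraction of free RNA, no mitochondrial limit and a mitochondrial limit of 5% were added after seeing the data. Adjusted p values of alternatives used statsmodels 0.14.6, and plots matplotlib 3.10.9.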

Results

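Nuclei of the area postrema and the nucleus tractus solitarius, brainstem regions that sense blood-borne and gut signals and take part in nausea and vomiting, were profiled in 4 rats 6 h after cisplatin, a platinum drug that crosslinks DNA. The 4 libraries held 77620846 to 106417740 UMIs, and 47.1% to 52.0% of these lay in called droplets. After filtering and removal of doublets, the 4 animals had medians of 2697 to 3332 UMIs over 33492 nuclei. Of these 31413 were named, among them 1583 patchy neurons that were counted in the shares and not tested. All 4 animals had received cisplatin, so the values describe the tissue after treatment and do not show what cisplatin changed.

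Neurons made up 50.2% ± 5.6 (SD, n = 4) of the named nuclei, and the largest glial class, oligodendrocytes, the cells that form myelin, 16.03% ± 3.51. Astrocytes made up 9.86% ± 1.997, oligodendrocyte precursors with 3.47% ± 0.47 and microglia or macrophages, the resident immune cells, with 2.82% ± 0.81. Choroid plexus nuclei, from the epithelium that secretes cerebrospinal fluid, reached 4.13% ± 1.52, vascular nuclei 1.59% ± 0.41, fibroblasts 1.75% ± 1.05, committed oligodendrocyte precursors 0.885% ± 0.184 and ependymal cells or tanycytes, which line the ventricle, 0.776% ± 0.171. A cluster led by Igfbp5, Wt1, Lmx1a, Reln, Aldh1a2 and Wif1 matched no marker list and is called the Wt1/Lmx1a cluster, with 3.47% ± 0.62. Among 15648 neurons, inhibitory clusters held 52.0% ± 4.5, glutamatergic clusters 27.5% ± 3.0, cholinergic motor clusters 6.52% ± 3.22 and unassigned clusters 14.1% ± 6.6. The glutamatergic clusters included N9, N21 and N11, which also had 6, 4 and 3 catecholaminergic markers raised. Patchy neurons, with 4.998% ± 3.551, were nearly missing from replicate 1 (0.116%, exact 95% interval 0.053% to 0.220%), which held 9 of these nuclei against 704, 515 and 355 in replicates 2, 3 and 4. Fibroblasts made up 0.360% of replicate 1 (0.239% to 0.520%) and 1.76% to 2.90% of the other animals.

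**Figure D1:**
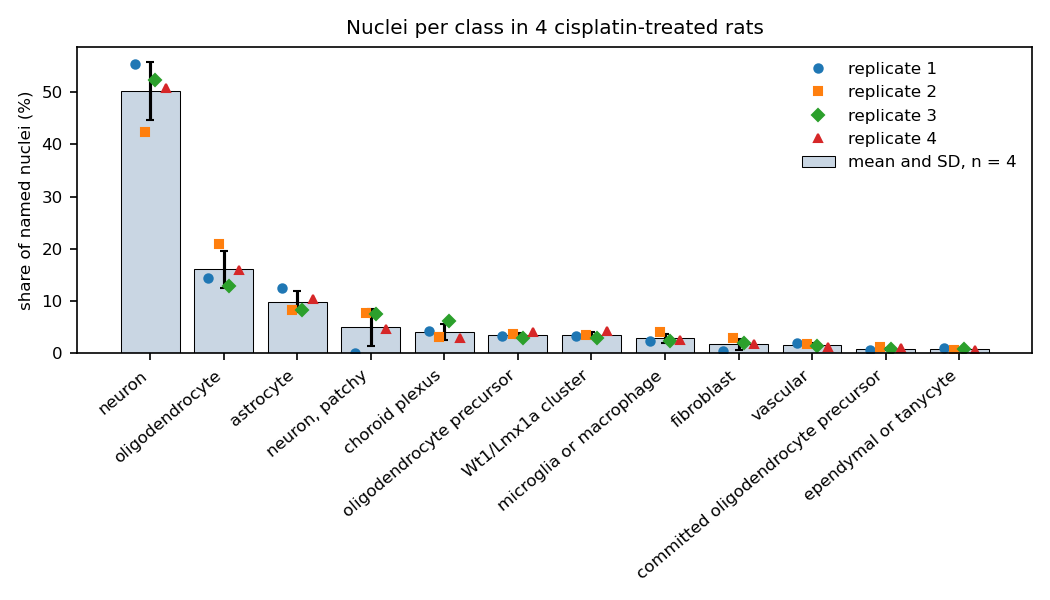
Share of named nuclei in each class, in percent, for 4 cisplatin-treated rats. Bars give the mean and SD and symbols the animals; neurons lie between 42.3% and 55.5%, and patchy neurons are at 0.116% in replicate 1.

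Vascular nuclei, which the first comparison sets against the mean of the other classes, carried the genes of the brain barrier. Cldn5, a tight junction protein of endothelium, was higher by a log2 fold change of 6.72 ± 0.11 (SE, adjusted p = 1.65e-45) at 1834 ± 377 CPM, and the transporters Slco1a4 and Abcg2 by 6.59 and 6.50, each in 4 of 4 animals. Immediate early genes, which respond to stimulation within minutes, were also high there. Klf4, a transcription factor of vessels, was higher by 5.06 ± 0.25 (82.2 ± 15.8 CPM), Ier2 by 3.43 and Dusp1, a phosphatase that limits MAP kinases, by 2.69. The synaptic gene Homer1 lay lower, at -0.91, and Fos was not called, at 0.47 ± 0.33. Cytokine response genes included Il1r1, the interleukin 1 receptor, at 4.12 ± 0.19, Nfkbia, the inhibitor of NF-kB, at 3.38 ± 0.12 and Lcn2, an acute-phase protein, at 3.03 ± 0.34. The metal-binding protein gene Mt1 was higher by 2.65 ± 0.14, and Sult1a1, a sulfotransferase, by 1.89 ± 0.17. Fkbp5, of the glucocorticoid list, was not called, at -0.27 ± 0.30.

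By camera, the barrier list (11 of 11 tested members higher, also 11 when adjusted over the list alone) had a median log2 fold change of 4.06 and an adjusted p of 2.55e-14 in vascular nuclei. The class was named from endothelial markers and its leading genes included Cldn5 and Slco1a4, so this call follows largely from the naming. The immediate early list (10 higher and 1 lower of 13; 11 and 1 adjusted over the list alone) had 1.58 and 0.00141, and the cytokine list (8 of 12 higher, the same count adjusted over the list alone) 0.77 and 0.00255. For the glucocorticoid list (9 of 15 higher, the same count adjusted over the list alone) they were 0.96 and 0.00202. These 4 calls held with an estimated correlation. Vascular nuclei and fibroblasts had the highest median mitochondrial shares of the classes, 8.75% and 8.38% against 4.00% in neurons, and neither had enough nuclei to be tested at a limit of 5%. Damage to nuclei was therefore not excluded as a source of the immediate early, cytokine and glucocorticoid calls in these 2 classes. The platinum, metallothionein and NRF2 list (9 higher and 2 lower of 17, the same counts adjusted over the list alone) had a median of 0.56 and an adjusted p of 0.0213, and was not called otherwise (adjusted p = 0.0961 with an estimated correlation). That call was also lost with no mitochondrial limit, at an adjusted p of 0.129 in a range of 0.0169 to 0.129 over its alternatives. Of 139 panel genes tested, 57 were higher and 15 lower in vascular nuclei, against 2789 and 2226 of all 12268 genes. The lower panel count was 7, 9 and 9 without replicates 2, 3 and 4. Plvap, which forms the diaphragms of fenestrated capillaries, was higher by 1.34 ± 0.36 in 3 of 4 animals, a call lost without replicate 4, where the value was 0.70, and with no mitochondrial limit, where it was 0.61. In choroid plexus Plvap was higher by 1.13 ± 0.28 in 4 of 4 animals (17.3 ± 12.9 CPM, under the 18.6 of empty droplets), a call lost without replicate 1, at 0.61.

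Fibroblasts carried receptors and adhesion molecules of inflammation, with Il1r1 higher by 4.04 ± 0.22, Vcam1, which binds leukocytes, by 3.05 ± 0.16 and Icam1, of the same function, by 2.25 ± 0.31, in 4 of 4 animals. Klf4 was higher by 3.82 ± 0.37 and Egr1, an immediate early transcription factor, by 1.72 ± 0.35, whereas Fos was not called, at 0.19 ± 0.41. Fkbp5, a chaperone induced by glucocorticoids, was higher by 2.15 ± 0.22 (63.4 ± 27.2 CPM) and Sult1a1 by 2.65 ± 0.18, and Slc47a1, a transporter that exports organic cations and platinum drugs, by 7.70 ± 0.30 (115 ± 24 CPM). The cytokine list was called (10 of 12 higher, 11 adjusted over the list alone, median 1.52, adjusted p = 4.02e-06), and the call held with an estimated correlation. The immediate early list (8 higher and 1 lower of 13, the same counts adjusted over the list alone, median 0.91) had an adjusted p of 0.0263 (adjusted p = 0.0961 with an estimated correlation). Without replicates 1, 2 and 3 it was 0.0653, 0.0539 and 0.0578, in a range of 0.00775 to 0.0961 over its alternatives. The glucocorticoid list (7 higher and 2 lower of 15, the same counts adjusted over the list alone, median 0.46) had 0.0474 (adjusted p = 0.191 with an estimated correlation). Without replicates 2, 3 and 4 it was 0.0523, 0.0578 and 0.0571. It was 0.0521 with doublets kept and 0.0721 at the higher clustering resolution, in a range of 0.00222 to 0.191, and the call was lost under 6 of 11 alternatives. Of 139 panel genes 41 were higher and 13 lower, against 1970 and 1628 of all 12268 genes. The lower panel count was 7, 7 and 8 without replicates 2, 3 and 4. Replicate 1 held 28 fibroblasts.

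The next comparison asked where p53 target genes, which respond to DNA damage, were expressed 6 h after a drug that crosslinks DNA. Gdf15 (ENSRNOG00000019661), the stress hormone that binds the receptor GFRAL, was higher in choroid plexus nuclei by 4.48 ± 0.20 (41.6 ± 6.7 CPM against 7.18 in empty droplets), in 4 of 4 animals. Cdkn1a (ENSRNOG00000000521), the p21 cell cycle inhibitor, was higher in choroid plexus by 2.58 ± 0.11 (101.2 ± 12.4 CPM), in vascular nuclei by 1.73 ± 0.15 (82.0 ± 26.3 CPM) and in the Wt1/Lmx1a cluster by 0.75 ± 0.16. Mdm2 (ENSRNOG00000006304), the ligase that degrades p53, was higher in ependymal cells or tanycytes by 2.60 ± 0.10 (526 ± 133 CPM) and in choroid plexus by 1.14 ± 0.09 (161 ± 70 CPM), and lower in vascular nuclei, by -0.87 ± 0.14. The death gene Pmaip1 was higher in vascular nuclei, at 6.62 ± 0.32 (58.5 ± 19.1 CPM). The antiproliferative gene Btg2 was higher in the Wt1/Lmx1a cluster, at 3.31 ± 0.13 (190 ± 51 CPM), and Eda2r, a receptor of the TNF family, in oligodendrocytes at 3.65 ± 0.24.

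Within these classes, Polk, a DNA polymerase that bypasses lesions, was higher in vascular nuclei by 2.69 and in ependymal cells by 2.002, and Btg2 in vascular nuclei by 2.28. Fas, a death receptor, was higher in ependymal cells by 1.97 and in the Wt1/Lmx1a cluster by 2.51, as was Tp53inp1 in that cluster, by 1.92. In choroid plexus Pmaip1 was higher by 1.99 at a level of 2.10 ± 0.84 CPM, a call lost without replicate 1, where the value was 1.81. Ddb2, a damage sensor, was lower, at -0.83, a call lost with a mitochondrial limit of 5%, at -0.03. In ependymal cells Cdkn1a was higher by 0.61 ± 0.23, a call lost without replicates 1, 2 and 4, where the values were 0.57, 0.61 and 0.56, and under 4 other alternatives, at 0.42 to 0.61. Neurons lay low for Cdkn1a, at -1.77 ± 0.15 (9.70 ± 2.25 CPM, under the 30.8 of empty droplets), and for Mdm2, at -0.77 ± 0.09. Gdf15 lay at -1.23 in neurons, a call lost without replicate 3, where the value was -0.75, and with a mitochondrial limit of 5%, at -1.01. Fas was lower in neurons by -2.94, a call lost without replicate 1, where it was -2.47, and Zmat3, an RNA-binding p53 target, was higher there, by 1.20.

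As a list, the 24 p53 targets tested passed the threshold in no class, with camera, and 5 of 11 classes had an unadjusted p under 0.05. In these 5, members were 12 higher and 5 lower in choroid plexus (adjusted p = 0.0798), 13 and 3 in the Wt1/Lmx1a cluster (0.0865), 1 and 6 in oligodendrocyte precursors (0.0874), 6 and 14 in neurons (0.124) and 2 and 7 in microglia or macrophages (0.128). Adjusted over the list alone they were 12 and 5, 14 and 3, 1 and 6, 6 and 14, and 2 and 7. Over all 12268 genes the same 5 classes had 3839 and 3649, 3191 and 2994, 1962 and 1907, 4432 and 4678, and 2384 and 1975. Vascular nuclei had 8 and 4 (9 and 5 adjusted over the list alone, adjusted p = 0.203) and ependymal cells 10 and 3 (the same, 0.445). In ependymal cells the median, -0.21, was of the opposite sign to the mean, 0.004, and to the test.

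**Figure D2:**
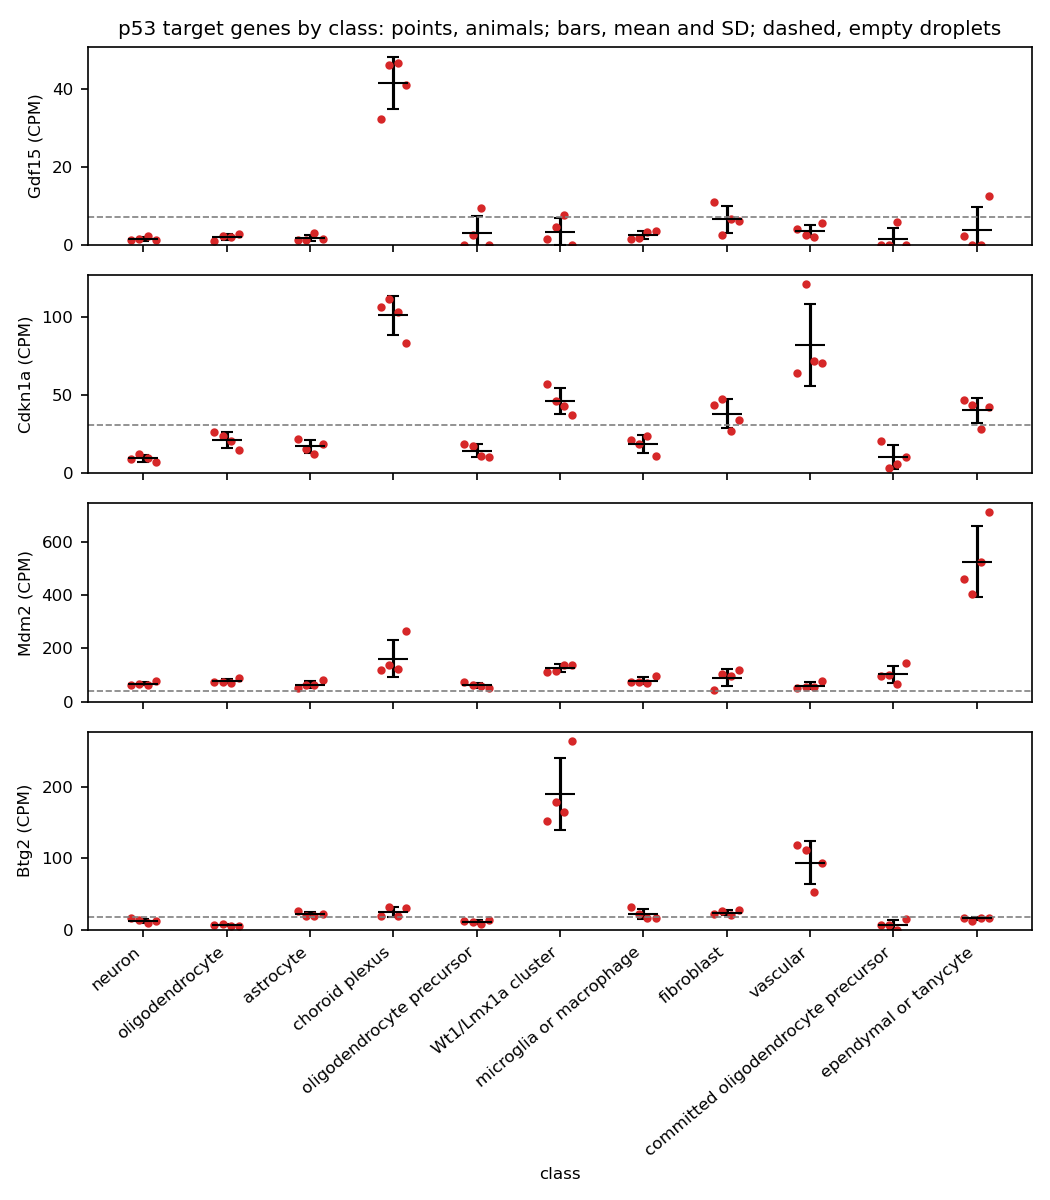
Levels of 4 p53 target genes in CPM for each class; points are the 4 animals, bars the mean and SD, and the dashed line the level in empty droplets. Gdf15 and Cdkn1a reach 41.6 and 101.2 CPM in choroid plexus, Mdm2 reaches 526 CPM in ependymal cells or tanycytes, and Btg2 reaches 190 CPM in the Wt1/Lmx1a cluster.

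Genes that handle platinum or repair its lesions included members higher in several classes. Slc31a1, the copper transporter that takes up cisplatin, was higher in choroid plexus by 2.81 ± 0.10 (89.4 ± 15.4 CPM). Slc7a11, the cystine transporter, was higher in the Wt1/Lmx1a cluster by 2.52 ± 0.14 and Hmox1, heme oxygenase, in the same cluster by 2.10 ± 0.23. The metallothionein gene Mt2A was higher in ependymal cells or tanycytes by 2.04 ± 0.16. Among repair genes, the damage kinases Atr and Chek2 were higher in ependymal cells by 3.19 ± 0.13 and 3.52 ± 0.31. The kinase Atm was higher in microglia or macrophages by 2.39 ± 0.08, and the damage sensor Ddb1 in choroid plexus by 1.36 ± 0.09. In neurons Slc7a11 lay lower, at -2.30 ± 0.18.

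The platinum list was lower in neurons (1 higher and 13 lower of 17, the same counts adjusted over the list alone, median -0.77). Its adjusted p was 0.00417 there (adjusted p = 0.0511 with an estimated correlation). In committed oligodendrocyte precursors 3 of 17 members were lower, and 1 was higher and 3 lower adjusted over the list alone, with a median of -0.61. There the adjusted p was 0.0474 (adjusted p = 0.161 with an estimated correlation). The latter call was lost without replicates 1, 2 and 4, at adjusted p of 0.100, 0.0565 and 0.0755. It was also lost with free RNA subtracted (0.0531), doublets kept (0.0896), no mitochondrial limit (0.0791) and a mitochondrial limit of 5% (0.278). In all 8 of 12 alternatives ended it, in a range of 0.0203 to 0.278. The crosslink and nucleotide excision repair list passed the threshold in no class by camera. Its largest count of higher members was in neurons (10 higher and 6 lower of 22, the same counts adjusted over the list alone, adjusted p = 0.757). Neurons also had the most calls over all 12268 genes tested, 4432 higher and 4678 lower, so that count alone does not set the list apart. By camera 1 class, vascular, had an unadjusted p under 0.05 (8 of 22 lower, the same count adjusted over the list alone, adjusted p = 0.124).

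Cytokine response, glucocorticoid-responsive and immediate early genes were also compared in neurons and glia. In neurons Nfkbia lay at -1.93 ± 0.19, and Fos, the immediate early gene used to mark active neurons, was higher, at 0.66 ± 0.15 (13.6 ± 2.1 CPM, near the 14.7 of empty droplets). In choroid plexus Fos was called lower, at -0.69 ± 0.30, in 3 of 4 animals. Oligodendrocytes carried Pdk4, a glucocorticoid-induced kinase, at 3.04 ± 0.27 and Arrdc2 at 2.94 ± 0.13, and of the glucocorticoid list 9 members were higher and 4 lower of 15 there (the same counts adjusted over the list alone, adjusted p = 0.124). Fkbp5 was higher in oligodendrocytes, astrocytes and microglia by 0.89, 0.56 and 0.63, and lower in choroid plexus, at -1.08 ± 0.26. Its call in astrocytes was lost without replicate 1 (0.26) and with a mitochondrial limit of 5% (0.49), and in microglia without replicate 4 (0.48) and without the replicate block (0.65). Microglia or macrophages carried Il6r, the interleukin 6 receptor, at 3.73 ± 0.13 and astrocytes Vcam1 at 2.25 ± 0.12.

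In neurons the cytokine list (1 higher and 11 lower of 12, the same counts adjusted over the list alone, median -1.52) had an adjusted p of 0.00746 (adjusted p = 0.0724 with an estimated correlation). The glucocorticoid list (1 and 11 of 15, the same adjusted over the list alone, median -1.29) had 0.00341 (adjusted p = 0.0516 with an estimated correlation). The barrier list (9 of 11 lower, the same adjusted over the list alone, median -1.54) had 0.0293 (adjusted p = 0.236 with an estimated correlation). The cytokine list was also lower in oligodendrocytes (10 of 12, the same adjusted over the list alone, median -0.82), at an adjusted p of 0.0198 (adjusted p = 0.0961 with an estimated correlation). In committed oligodendrocyte precursors it was lower (3 of 12, the same adjusted over the list alone, median -0.89), at 0.0107 (adjusted p = 0.0792 with an estimated correlation). The latter had an adjusted p of 0.0653 without replicate 1, in a range of 0.00391 to 0.352 over its alternatives. In oligodendrocyte precursors the barrier list was lower (7 of 11, the same adjusted over the list alone, median -0.79), at 0.0474 (adjusted p = 0.267 with an estimated correlation). It lost this call without replicates 2, 3 and 4, at 0.0526, 0.0719 and 0.0995. It was also lost with features centred within animals (0.0660), at the higher clustering resolution (0.0743), with no mitochondrial limit (0.0512) and with a limit of 5% (0.278). In all 8 of 12 alternatives ended the call, in a range of 0.00716 to 0.278. Of all 99 pairs of list and class 20 were called, 6 of them also with an estimated correlation. With a mitochondrial limit of 5%, which left 8 of the 11 classes, camera called 0 of 72 pairs, and 15 had an unadjusted p under 0.05. The median, mean and test differed in sign in 16 of the 99 pairs, none of them among the 20 calls.

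**Figure D3:**
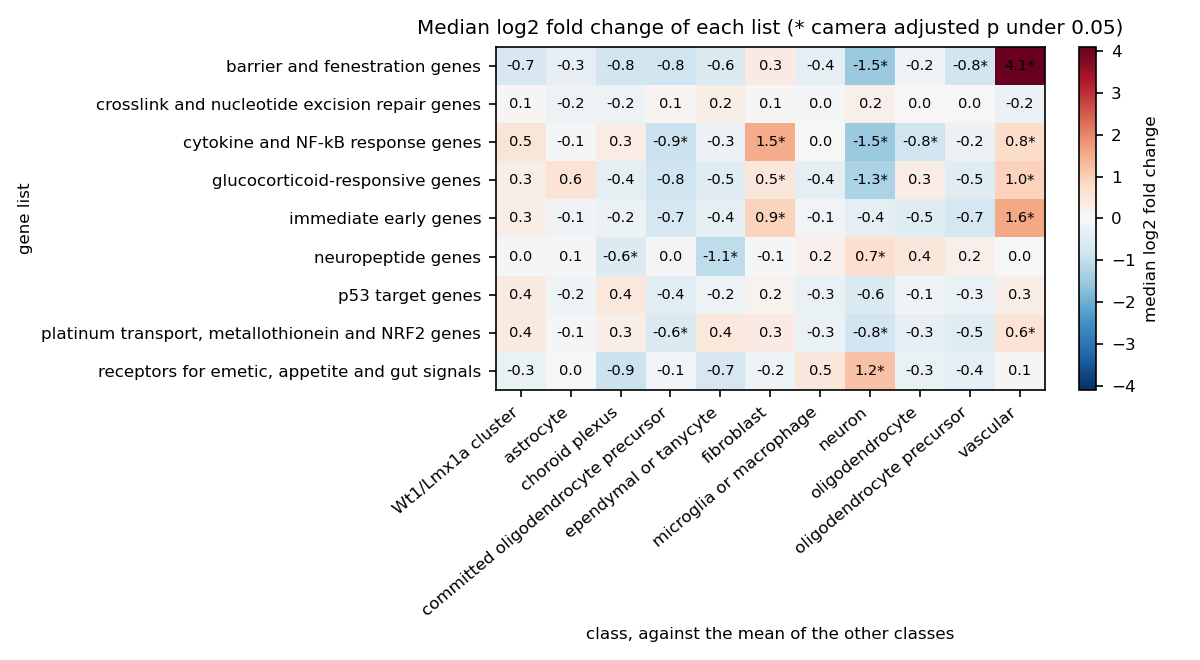
Median log2 fold change of each of the 9 gene lists in each class against the mean of the other classes; asterisks mark the 20 pairs called by camera at a correlation of 0.01. The barrier list in vascular nuclei reaches 4.06, and 6 calls held with an estimated correlation.

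Of 17 receptors for emetic, appetite and gut signals tested, 13 were higher and 2 lower in neurons, the same adjusted over the list alone (median 1.22). The list had an adjusted p of 0.0361 (adjusted p = 0.0757 with an estimated correlation). The call was also lost with doublets kept and at the higher clustering resolution, at 0.0521 and 0.0649, in a range of 0.0174 to 0.278 over its alternatives. Tacr1, the substance P receptor that antiemetic drugs block, was higher by 4.34 ± 0.24 and Calcr (ENSRNOG00000010053), the calcitonin and amylin receptor, by 3.68 ± 0.28. Htr4, a serotonin receptor, was higher by 3.42 ± 0.13 and Gfral (ENSRNOG00000032063), the receptor of GDF15, by 2.64 ± 0.18 (27.3 ± 2.2 CPM), each in 4 of 4 animals. Casr (ENSRNOG00000002265), the calcium-sensing receptor, was higher in neurons by 1.86 ± 0.37 and in committed oligodendrocyte precursors by 6.66 ± 0.43 (84.4 ± 43.1 CPM); with a mitochondrial limit of 5% the neuron call was lost, at 0.81. Other classes carried Htr2c, in choroid plexus at 6.21 ± 0.16, Agtr1a, the angiotensin receptor, in ependymal cells at 3.41 ± 0.32, and Ret, the coreceptor of GFRAL, in astrocytes at 1.56 ± 0.12. Calcrl and its partner Ramp1, which form the CGRP receptor, were higher in oligodendrocyte precursors, at 4.03 ± 0.12 and 1.85 ± 0.11. Neuropeptide genes higher in neurons included Nmu at 2.33 ± 0.15 and Bdnf, a neurotrophin, at 2.03 ± 0.13. Glp1r and Htr3a had too few counts to be tested between classes.

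In neurons the neuropeptide list (14 higher and 1 lower of 16, the same adjusted over the list alone, median 0.67) had an adjusted p of 0.0199 (adjusted p = 0.0676 with an estimated correlation). In oligodendrocytes 11 members were higher and 0 lower (adjusted p = 0.0786), and in microglia or macrophages 6 and 1 (adjusted p = 0.2504), the same adjusted over the list alone in both. The list was lower in ependymal cells (1 higher and 11 lower of 16; 1 and 13 adjusted over the list alone; median -1.06, adjusted p = 0.00326). That call held with an estimated correlation and was lost with free RNA subtracted, at 0.108 in a range of 0.000835 to 0.108. In choroid plexus it was lower (10 of 16, the same adjusted over the list alone, median -0.58), at 0.0474 (adjusted p = 0.107 with an estimated correlation). This call was lost without replicate 1, 2, 3 or 4, at 0.0763, 0.0523, 0.0512 and 0.0561, with free RNA subtracted, at 0.177, with features centred within animals, at 0.0522, and with a mitochondrial limit of 5%, at 0.105. In all 8 of 12 alternatives ended it, in a range of 0.0170 to 0.177. Neuropeptide RNA was abundant in empty droplets, where Penk reached 558 CPM against 387 ± 55 in neurons and Sst 605 against 297 ± 58.

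Microglia or macrophages showed 7 of 17 tested receptor genes higher, Oprm1, Calcr, Tacr1, Calcrl, Drd2, Gfral and Htr4. Oprm1, the opioid receptor, lay at 2.22 ± 0.14, Gfral at 2.01 ± 0.33 and Htr4 at 1.897 ± 0.234 (7 adjusted over the list alone, list adjusted p = 0.124). The same nuclei held the neuron markers Syt1, Grin1, Gabrb2, Snhg11 and Celf4 at a median of 49.5% of the neuron level. At the higher clustering resolution and with no mitochondrial limit these markers lay at 14.9% and 13.1%, and of the 7 genes only Calcrl and Oprm1 were still called. Gfral then lay at 0.75 and 0.31, Htr4 at -1.02 and -0.73, Tacr1 at -1.16 and -0.12, Calcr at 0.47 and 0.87, and Drd2 at 0.14 and -0.43. Calcr was also not called without replicate 1 (1.76), Tacr1 without replicate 3 (1.65) and Drd2 without replicate 2 (1.06). At a fixed limit of 1000 UMIs these 3 genes lay at 1.42, 0.97 and 0.50 and were not called, and with doublets kept Tacr1 was not called, at 0.74.

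Receptor genes differed in both directions between inhibitory and glutamatergic neurons of the same animals. The glutamatergic side included the clusters N9, N21 and N11, which also carried catecholaminergic markers. Of 24 receptor genes tested, 9 were higher and 13 lower in inhibitory neurons, the same adjusted over the list alone, and the list was not called by camera (adjusted p = 0.112). Sctr, the secretin receptor, was lower in inhibitory neurons by -4.39 ± 0.14, Calcr by -4.17 ± 0.18 and Casr by -3.99 ± 0.23. Gfral was lower by -2.92 ± 0.09 and Glp1r (ENSRNOG00000001152), the receptor of the satiety hormone GLP-1, by -1.32 ± 0.25, in 4 of 4 animals. Drd2, the dopamine receptor, was higher by 1.87 ± 0.11, Ret by 0.73 ± 0.08, Htr3a, the serotonin-gated channel that antiemetic drugs block, by 0.99 ± 0.28 and Ptger3, a prostaglandin receptor, by 0.84 ± 0.25. Among transmitter peptides, Bdnf lay at -3.08, Nts, neurotensin, at -2.88 and Grp at -2.31, whereas Pnoc, the nociceptin precursor, was higher by 1.73, Sst, somatostatin, by 1.07 and Penk, the enkephalin precursor, by 0.84. Cdkn1a, Mdm2 and Fos did not pass the test, with values of -0.09 ± 0.14, -0.10 ± 0.06 and 0.17 ± 0.14. Gdf15 was not tested between these neurons.

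The neuropeptide list was lower in inhibitory neurons (3 higher and 12 lower of 19, the same adjusted over the list alone, median -0.66, adjusted p = 0.000212; adjusted p = 0.175 with an estimated correlation). Few members of the lists other than peptides and receptors passed the test, with an adjusted p of 0.985 for each list. Those were Homer1 at 0.56 and Nr4a3 at -0.65 of 12 immediate early genes, Phlda3 at 0.33 and Btg2 at -0.38 of 20 p53 targets, and Zbtb16 at 0.91 and Fkbp5 at -0.65 of 14 glucocorticoid-responsive genes. Of 24 repair genes 3 were higher, with Fanca at 0.98. The barrier list had 2 higher, with Plvap at 0.99, and 1 lower of 11, and the cytokine list 3 higher, with Il1r1 at 1.20 and Il6r at 1.18, and 1 lower of 10. The platinum list had 2 higher, with Abcc4 at 0.70, and 1 lower, Slc31a1 at -0.79, of 18. Adjusted over the list alone the p53 list kept 1 higher, the platinum list had 1 and 1, and the other lists had the same counts. Medians and means differed in sign for the barrier list (-0.009 and 0.097), the cytokine list (-0.044 and 0.186) and the immediate early list (0.068 and -0.018).

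Over 144 panel genes 25 were higher and 31 lower with the animal as a block, against 2175 and 1742 of all 13600 genes tested. Without the block 12 and 23 panel genes were, and by the DESeq2 Wald test 14 and 25. Without the block the calls of Htr3a, Ptger3, Il6r, Nr4a3, Abcc4, Phlda3 and Btg2 were lost, and by the Wald test those of Il1r1 and of the same genes except Abcc4. Among these, Htr3a was also lost without replicates 1 and 4, where it lay at 0.90 and 0.83, and Ptger3 without replicates 3 and 4, at 0.63 and 0.87. Il6r was lost without replicates 3 and 4, at 1.01 and 0.85, and Btg2 without replicates 1, 2 and 3, at -0.27, -0.35 and -0.40. Doublets kept ended the call of Ptger3, at 0.59, and the higher clustering resolution those of Htr3a, Nr4a3 and Btg2, at 0.71, -0.22 and -0.28. Fos lay at -0.03 without replicate 4.

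Among clusters of neurons, N21, led by Gfral, Ddc, Slc6a2, Casr and Nts, carried Gfral at 387 ± 14 CPM, higher than the mean of the other clusters by 5.04 ± 0.10 (adjusted p = 1.27e-87) in 4 of 4 animals. It also carried Casr, higher by 7.08 ± 0.27, Sctr by 4.94 ± 0.20, Glp1r by 4.87 ± 0.33 and Calcr by 3.95 ± 0.30. N9, led by Calcr and the catecholamine enzymes Ddc, Th and Dbh, had Calcr higher by 6.64 ± 0.19 (307 ± 49 CPM), Gfral by 3.13 ± 0.17 (109 ± 21 CPM) and Agtr1a by 2.50 ± 0.27. N11, led by Sctr and Npff, had Sctr higher by 6.54 ± 0.18, Gipr, the receptor of the gut hormone GIP, by 4.76 ± 0.25, Casr by 4.29, Glp1r by 3.45, Calcr by 1.99 and Gfral by 1.903 ± 0.245 (43.4 ± 24.1 CPM). N14, which expressed Tph2, the enzyme of serotonin synthesis, had Calcr higher by 5.27 ± 0.24.

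In other clusters, Gipr was higher in the inhibitory cluster N0, at 5.25 ± 0.17, and Drd2 in N13, at 3.56 ± 0.20 (3 animals). Ret was higher in the motor cluster N20 at 4.004 ± 0.111, and Chrm3, a muscarinic receptor, in N16 at 3.38 ± 0.39. Tacr1 was higher in N2 at 2.58 ± 0.24 and Glp1r in the inhibitory cluster N3 at 2.04 ± 0.36. Over 26 clusters and 20 receptor genes tested, 124 pairs were higher and 69 lower; without 1 replicate 115 to 125 were higher and 49 to 62 lower. In N21 Cdkn1a and Fos did not pass the test, at 0.04 ± 0.32 and -0.20 ± 0.36. Cdkn1a lay at 0.29 without replicate 1 and -0.08 without replicate 2, and Fos at -0.70 without replicate 2 and 0.23 without replicate 4. Mdm2 lay at 0.28 ± 0.11 and was called without replicate 3 and with free RNA subtracted, at 0.37 in both. In the other Gfral-bearing clusters Fos went opposite ways. It was higher in N9, at 1.77 ± 0.27 (36.3 ± 10.8 CPM against 14.7 in empty droplets), and lower in N11, at -1.70 ± 0.61, from 4 UMIs. The N11 call was lost without replicates 1, 3 and 4, at -1.62, -1.64 and -1.28, and by the DESeq2 Wald test, at -1.75. Over 26 clusters Fos was higher in 7, among them N5 at 1.21 ± 0.21, and lower in 4; Cdkn1a was higher in 2, and Mdm2 higher in 3 and lower in 3.

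**Figure D4:**
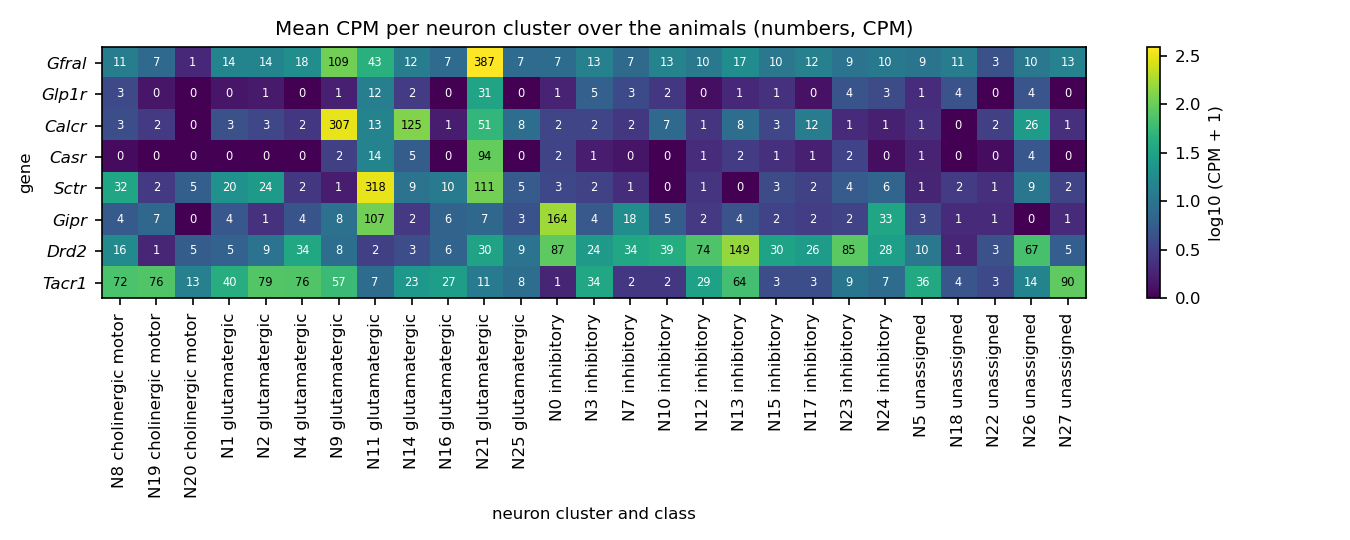
Mean CPM of 8 receptor genes in each neuron cluster over the animals, with cluster and class on the horizontal axis, colour on a log10 scale and the rounded CPM in each cell. Gfral reaches 387 CPM in N21, 109 in N9 and 43.4 in N11, and Calcr 307 CPM in N9.

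At an equal depth of 1500 UMIs per nucleus, Gfral was detected in 22.3% ± 1.0 of N21 nuclei, 9.26% ± 1.72 of N9 and 5.05% ± 1.78 of N11. In oligodendrocytes, which should lack it, the share was 0.424% ± 0.142 (median depths before thinning 2929, 3824, 3312 and 2158.5 UMIs). Over all neurons the share was 2.87% ± 0.31. Calcr was detected in 20.3% ± 1.9 of N9, 14.6% ± 1.7 of N14 and 5.20% ± 0.78 of N21, and in 0.116% of oligodendrocytes. Casr was detected in 9.64% ± 2.48 and Glp1r in 3.97% ± 2.08 of N21, and in 0.139% and 0.106% of oligodendrocytes. With all UMIs, 860 of 15648 neurons held Gfral.

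Some receptors of the emetic circuit met in the same neurons more often than their single frequencies over all neurons gave. Gfral and Casr occurred together in 67 neurons against 8.52 expected, a ratio of 7.87, Gfral and Calcr in 86 against 22.7 (3.78), and Gfral and Glp1r in 34 against 9.22 (3.69). Calcr and Casr met in 39 against 3.99 (9.78), Glp1r and Casr in 20 against 1.58 (12.6), and Glp1r and Calcr in 13 against 4.15 (3.13). These 6 pairs lay above expectation in 4 of 4 animals, with an exact sign-flip p of 0.13, the smallest that 4 animals allow, and an adjusted p of 0.313 over 15 pairs, so none passed the correction. The expected numbers were taken over all neurons and not within clusters. N21 alone held 226 of the 860 neurons with Gfral and 112 of the 163 with Casr. The ratios therefore also reflect that these genes share clusters, and whether they meet more often within a cluster was not tested. Lepr, the leptin receptor, was found in 1 of 15648 neurons, too few for its pairs to be read. Ramp3, a partner of the calcitonin receptor, was detected at equal depth in 1.83% of neurons and 2.93% of oligodendrocytes, so its pairs cannot be read either.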

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

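The tests of missing cerebellar-marker neurons, of free RNA in microglia or macrophages and in choroid plexus, of abundant genes in choroid plexus, of Calcrl and Oprm1, and of receptor calls at the higher clustering resolution were chosen only after the result was seen.

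In 4 of 35 groups of 4 animals examined, 1 animal lay far from the others; chance alone gives about 1 in 20 such groups. The share of microglia or macrophages was 4.02% in replicate 2 (exact 95% interval 3.62% to 4.44%) and 2.28% to 2.56% in the others. Glutamatergic clusters held 31.9% of the neurons of replicate 4 and 25.5% to 26.4% in the others. Ttr, the choroid plexus transport protein, reached 100581 CPM in the empty droplets of replicate 3. Mdm2 in choroid plexus reached 266 CPM in replicate 4.

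The patchy neurons nearly missing from replicate 1 carried markers of the cerebellum, which lies above these nuclei. Their loss at the calling of nuclei is argued against by the empty droplets, where a list of 5 such markers (Gabra6, Cbln3, Pcp2, Calb1 and Neurod1) lay in replicate 1 at a median ratio of 0.076 to the lowest other animal. Of these, Pcp2 lay at 4.06 CPM against 182 to 389, and Calb1, which other neurons express too, at a ratio of 0.670. Shallower sequencing is argued against by the UMIs per nucleus, at 1.14 times the lowest other animal. Over all droplets the ratio was 0.129, so less cerebellar tissue in the punches of replicate 1 may account for the pattern. The cluster led by Arhgef33, Itpr1 and Dgkh, left out for its doublet scores, was missing from replicate 1 too (0, 22, 21 and 16 nuclei). Whether that cluster belongs to the same pattern was not tested, nor was any biological explanation.

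In microglia or macrophages 7 receptor genes were higher, and free RNA as the cause is argued against, since they lay at a median of 3.47 times their level in empty droplets. Nuclei with more neuron marker UMIs held a receptor UMI in 21.6% of cases and the others in 13.9%, a ratio of 1.55. By a bound set before this ratio was computed, a ratio under 2 was to count against neuron RNA, and the result met it. The ratio ran from 1.00 to 4.28 over the animals, on both sides of the bound. That spread was not part of the rule, but with it the ratio alone does not settle the matter. At the higher clustering resolution, where neuron markers fell from 49.5% to 14.9% of the neuron level, 2 of the 7 genes, Calcrl and Oprm1, were still called, so neuron RNA in the same droplets may account for Tacr1, Drd2 and Htr4. Calcrl and Oprm1 lay at 119.0% of the neuron level or more, above the 57.1% reached by the neuron markers, which argues against neuron RNA as their source; Gfral and Calcr, at 0.712 and 0.648 of the neuron level, lay above the markers too but lost their calls, so for them neuron RNA stays open. No biological explanation was tested.

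In choroid plexus 12 p53 target genes were higher. All 12 were still called after free RNA was subtracted, which by the bound of this test argues against free RNA. However, the subtraction took the same number of UMIs from each nucleus of a library, and so a larger part from small nuclei. It could widen the contrast with classes of smaller nuclei, and Gdf15 went from 4.48 to 5.54. Phlda3, Gadd45a and Pmaip1 lay below empty droplets, as with Phlda3 at 91.1 against 133 CPM, so for them free RNA stays open. Abundant genes such as Ttr, which take a large part of the counts and could distort the scaling, are argued against for 8 of the 12, which lay above the mean of the other classes in CPM of the plain totals, with Gdf15 at 41.6 against 3.04. Of the 8, Mdm2 lay at 161 against 125 CPM, but replicate 4 reached 266 and the next highest animal 137. For Mdm2 this argument therefore leans on replicate 4. The other 4 of the 12, Gadd45a, Sesn2, Btg2 and Pmaip1, lay under the mean of the other classes, as with Pmaip1 at 2.10 against 6.48. For them this comparison cannot decide. The plain mean follows a single high class, such as vascular nuclei for Pmaip1, whereas the fold change uses a mean of logs. Abundant genes also lower the plain CPM, so the scaling and a higher level were not told apart for these 4. Whether cisplatin raised these genes was not tested, since all 4 animals had received it.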

How the results depend on the processing

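Subtraction of free RNA, no mitochondrial limit and a mitochondrial limit of 5% were chosen after seeing the data. Of 634 comparisons of shares, counts and co-detection ratios with an alternative, 579 stayed within the spread between animals or within 1.5 times the count. Among them were all 60 of co-detection and all 18 of receptor calls by cluster. The mean share with a replicate left out always stays within that spread by arithmetic, so those comparisons are no evidence of stability. Of 2029 comparisons of a named gene and class, 1950 kept their direction and side of the threshold, 66 lost a call, 2 gained one and 11 changed sign. Genes named for the largest fold changes were already called and on the same side in every animal. That choice favours stability in this count. Depth limits the rarest receptors, such as Glp1r, found in 161 of 15648 neurons, and classes with few nuclei. Clustering and calling alternatives were not run for the neuron clusters.

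The cause was not tested for any change that follows, except where fewer classes, nuclei or replicates are named. A mitochondrial limit of 5%, which left 8 of 11 classes with enough nuclei, gave shares of 2.09% for the Wt1/Lmx1a cluster (3.47% in the report), 4.65% for astrocytes, 1.98% for choroid plexus, 1.10% for committed oligodendrocyte precursors, 0.311% for ependymal cells, 4.11% for microglia, 69.8% for neurons, 8.49% for oligodendrocytes, 2.38% for oligodendrocyte precursors and 0.578% for vascular nuclei, and 47.2% of neurons as inhibitory. Calls fell to 175 pairs higher and 137 lower, with 12 lower in astrocytes, 25 lower in choroid plexus, 7 lower in committed precursors, 12 lower in microglia, 11 lower in oligodendrocytes and 11 higher and 10 lower in oligodendrocyte precursors; list calls by camera fell to 0 (15 of 72 at an unadjusted p under 0.05), and Fos in inhibitory neurons lay at -0.001.

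With no mitochondrial limit, astrocytes made up 13.7%, ependymal cells 1.02%, neurons 43.2% and vascular nuclei 2.61%; motor clusters held 10.98% and glutamatergic clusters 24.01% of neurons. Committed precursors then had 12 genes higher and 28 lower, Htr4, Tacr1 and Drd2 in microglia lay at -0.73, -0.12 and -0.43, and Cdkn1a in inhibitory neurons at 0.018. A fixed limit of 1000 UMIs gave 5.38% microglia, 40.9% neurons, 22.7% oligodendrocytes and 10.2% of neurons in motor clusters. Keeping doublets gave 1.18% committed precursors with 11 genes higher, 4.02% microglia and 56.9% of neurons as inhibitory. The higher clustering resolution gave 2.01% microglia with 10 genes lower, Htr4 at -1.02 and Tacr1 at -1.16, 45.6% of neurons as inhibitory and 21.04% as unassigned. Centring the features moved Cdkn1a in inhibitory neurons to 0.010.

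Without the replicate block, 8 genes were lower in fibroblasts (13 with it), and 12 genes were higher in inhibitory neurons (25 with it), against 14 by the DESeq2 Wald test. With no filter on low counts 73 genes were higher in neurons, since more genes were tested; with free RNA subtracted 23 were lower in ependymal cells; and with an estimated correlation 6 list calls were left of 20. Leaving out 1 replicate gave 9 to 17 genes lower in committed precursors, 7 to 12 in fibroblasts and 7 to 11 in vascular nuclei. Fos in inhibitory neurons then lay between -0.031 and 0.276, and in N21 Cdkn1a between -0.082 and 0.287 and Fos between -0.700 and 0.228. Leaving out 1 replicate left 15 to 16 list calls in all.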

Other observations

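The splits and the tests of lists in Gfral-bearing clusters and in vascular nuclei were written before the results were seen. The tests of lists by neuron cluster were not part of the planned design. The genes of N20 and N1 and the Gcg cluster were picked afterwards.

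The motor cluster N20 (428 nuclei) had 39 of 123 panel genes higher and 32 lower than the mean of the other neuron clusters, and of all 10905 genes tested 3995 higher and 3850 lower. None of the 9 lists was called there, with adjusted p of 0.466 or more. Calca and Calcb, which encode the peptide CGRP, were higher by 6.10 ± 0.08 (2427 ± 771 CPM) and 5.64 ± 0.14, and Cck by 2.17 ± 0.19. The immediate early gene Jun was higher by 2.60 ± 0.15 (140 ± 20 CPM against 73.6 in empty droplets), and the glucocorticoid-responsive genes Bcl6 and Tsc22d3 by 3.06 ± 0.26 and 3.02 ± 0.11, in 4 of 4 animals. Of 20 p53 targets 7 were higher and 6 lower, the same adjusted over the list alone (adjusted p = 0.981). Mdm2 was lower, at -0.87 ± 0.21, and Phlda3 was higher by 2.24 ± 0.14, Gadd45a by 2.04 ± 0.25 and Ccng1 by 2.02 ± 0.19, at 166, 37.3 and 65.1 CPM against 133, 36.3 and 68.1 in empty droplets. The median mitochondrial share was 9.23% in N20 and 4.00% in all neurons. Replicate 3 held 20 N20 nuclei, the lowest number allowed in a sum, against 193, 128 and 87 in replicates 1, 2 and 4. Its TMM factor in N20 was 1.03, against 0.669, 0.637 and 0.789.

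N1, a glutamatergic cluster, carried Gal, the galanin precursor, higher by 3.77 ± 0.12 and Grp by 3.13 ± 0.17, and the neuropeptide list was called there (10 higher and 1 lower of 19, the same adjusted over the list alone, median 0.70, adjusted p = 2.58e-07 over 234 pairs of list and cluster, camera), also with an estimated correlation. The receptor list was called in N21 (12 higher and 2 lower of 20, the same adjusted over the list alone, median 0.69, adjusted p = 2.82e-05), also with an estimated correlation. Of the other calls by cluster, the receptor list was lower in N22 (2 higher and 9 lower of 20, the same adjusted over the list alone, adjusted p = 0.00707). The neuropeptide list was higher in N4 (adjusted p = 0.0130) and lower in N3, N8, N18, N19, N22 and N23 (adjusted p of 0.00131 to 0.0357; N18 and N19 in 3 animals), and these calls too held with an estimated correlation. A cluster led by Gcg, the GLP-1 precursor, N6, held 30 nuclei, with 6, 14, 4 and 6 in replicates 1 to 4, and was too small to be tested.

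Chance was examined by regrouping the nuclei's sums. With classes shuffled within animals, 1 of 40 groupings, the real one, gave as many called pairs of class and panel gene (732, highest other 47). With clusters shuffled, pairs of cluster and receptor gene at or below the largest unadjusted p called were counted. There 1 of 24 groupings, the real one, gave as many (217, highest other 50). The 8 sums of inhibitory and glutamatergic neurons were split in 35 ways and fitted without a block. Of these, 1, the real one, gave as many panel genes (35, highest other 2). With the animal block, the real split gave 56 and the highest other of the 8 splits that part every pair 0. These 8 are too few for a share under 0.05. By the bounds set beforehand the other shares counted against chance. However, the classes and clusters had been cut from the expression of these same nuclei, so the real grouping was bound to part the sums most. The regroupings therefore cannot decide whether panel or receptor genes differ beyond what clustering itself brings.

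Neurons of the area postrema lie outside the blood-brain barrier, and it was asked whether Gfral-bearing clusters (N21, N9 and N11) carried more p53 target RNA than 6 other clusters called glutamatergic. N21, N9 and N11 also had 4, 6 and 3 catecholaminergic markers raised, against 0 to 2 in the 6 others, so the 2 sides differ in more than Gfral. Punches of the area postrema and the nucleus tractus solitarius were pooled, so which clusters lie in the area postrema is not known. The comparison therefore does not set neurons outside the barrier against neurons inside it. In limma's camera test 3 of 20 genes were higher and the list's unadjusted p was 0.168 (adjusted p = 0.639 over 9 lists). For immediate early genes 1 was higher and 1 lower of 10, and the unadjusted p was 0.354 (adjusted p = 0.639). Vessel cells meet blood-borne cisplatin first, and for p53 targets in vascular nuclei the unadjusted p was 0.08001. The bound set beforehand read a p of 0.05 or more as evidence against each idea; it was wrong, since a missed threshold excludes no difference, so all 3 stay open.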
